A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

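Expression was measured on 36 arrays of yeast in continuous culture, 12 positions in each of 3 cycles, and every array was mapped to its position and cycle from its description. The deposited values are intensities per probe set, on a linear scale. How the authors summarised probes, and with which software, is not given in the sources used here. From the deposited values, the median of each array is exactly 1, so each intensity is a multiple of the array median. For each array a factor between 80.9 and 101.6 turned the 1500 lowest values into multiples of 0.1 within a tolerance of 0.02, for 100% of them. The mean without the top and bottom 2% then lay between 250.14 and 250.21 on every array, so the intensities look as if an earlier step had scaled each array to one trimmed mean; this is an inference from the values. In deposited units the trimmed mean lay between 2.46 and 3.09. There were 381 values equal to 0, and no detection calls were used here.

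Of 9335 probe sets, 6504 had 1 gene symbol in the platform annotation given with the data, 328 had several, 2443 were unlisted there, and 60 were controls. The annotation can be old, and symbols were updated through the gene table of the R64 assembly, which was used only for names and for which genes are neighbours. Tests used the 5656 genes with a symbol, each represented by its probe set with the highest mean; 315 genes had a second probe set. Of 114 genes with at least 2-fold swing and a second probe set, 106 had that probe set called with a peak within 1.5 intervals and 8 did not. Values were taken as log2(value + 0.0516), where the pseudocount is the 10th percentile of positive values, so that a fold change is on that scale and is understated for dim genes. No further scaling was applied.

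Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Genes were tested with limma's moderated F test of cosine and sine terms with a period of 12 intervals, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. A swing is the fitted peak-to-trough difference in log2, which is never negative and so lies above 0 by chance, and its SE is the approximate error of the fitted terms. Second harmonics used added terms with a period of 6 intervals. Differences between cycles used a cycle factor beside a 12-level position factor, and differences of swing used the interaction of cycle with the cosine terms. Camera compared each position with the mean of the other positions for 29 gene lists. Peak times of lists came from a cosine fit to the list mean within each cycle. Isoenzyme pairs were tested on the difference of their log2 values, which compares courses and not levels.

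The groups, tests, gene lists, isoenzyme pairs and the rule for named genes were fixed before the data were examined. The rule took the 6 genes with the largest swing among called genes above the dimmest 25% of genes, for each of 4 parts of the cycle, if their peak fell in that part in each cycle. It also took the 2 members with the largest swing and the 1 with the smallest in each list, again above the dimmest 25%, both genes of the 8 pairs that differed most, and up to 5 genes that rose and 5 that fell between cycles. It further took the 5 genes with the largest 6-interval swing among those where it exceeded the 12-interval swing, up to 5 genes whose swing differed between cycles, and the 3 markers MRPL10, POX1 and RPL17B. Together these were 124 genes, of which the text gives a part.

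Each test was first tested on simulated data made from the means and residual spreads of the real genes. The noise was drawn independently for each gene and the added swings were pure cosines. Effects shared by the genes of an array and shifts of timing were therefore not simulated, and the real tests may do less well. Among genes given a swing of 1 log2, 98% were recovered by the test for cycling, and 46% of those given 0.5 log2. There were 8 false calls among the genes left unchanged. A 12-interval swing of 1 log2 present only in cycle 3 was recovered in 22% of genes and one of 2 log2 in 86%, so small differences of swing between cycles would be missed. A level shift of 0.5 log2 in cycle 3 was recovered in 66%. For isoenzyme pairs, the first simulation recovered 8 of 10 changed pairs with 2 false calls, and a series of 200 simulations recovered 9.27 on average, with 2.53% of the calls false.

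Alternatives covered the scaling between arrays, the pseudocount, the dim genes, the probe choice, single cycles and arrays left out, the error model and the test; the closing section gives their effect. Predictions for the tests of explanations were written down before each test was run, and those on a constant period and on shared ribosomal RNA after the values they rest on had been seen. For 5 of these tests the verdict was made more cautious after their values had been seen, so that an explanation which the written rule would have excluded was left open; the closing section names them. For the second harmonic, regroupings of whole arrays were set aside in the same way, and an exchange of what the 12-interval cosine leaves was added with its rule written before it was run. The neighbouring-gene test was first run on genes with at least 2-fold swing, and was then run on all cycling genes, as its prediction stated.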

Results

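Gene expression was measured in the budding yeast Saccharomyces cerevisiae in continuous culture, where it passes through a repeating metabolic cycle. The 36 Affymetrix arrays followed 3 successive cycles, each divided into 12 intervals of about 25 min, with 1 array per interval. The arrays of the same position in the 3 cycles formed a group, which gave 12 groups of 3 arrays. The labels do not name separate cultures, so the p-values measure only the spread between these arrays. Each value is a probe-set intensity expressed as a multiple of its array's median. The number of arrays limits the precision. Arrays of the same position had a median correlation across genes of 0.978, with a lowest value of 0.864, and all 630 pairs of arrays had a median of 0.913. The comparisons asked which genes followed the cycle, when each group of genes was highest, and whether the cycles differed.

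Most of the measured transcriptome followed the cycle. Of 5656 genes tested, 4456 (78.8%) fitted a cosine with a period of 12 intervals at an adjusted p under 0.05 in limma, and 2155 (38.1%) did so with a fitted peak-to-trough swing of at least 2-fold. A swing of at least 4-fold was found for 601 genes and of at least 8-fold for 150, while 1200 genes were not called. The mean of the bacterial spike controls swung by 0.520 log2 (permutation p = 0.0112), so a swing of that size need not reflect yeast expression. The 3 genes chosen in advance as markers swung at different times. They were already known as markers of the 3 phases of this system, so this is no independent check. RPL17B, a protein of the cytosolic ribosome, had a fitted peak at position 8.79 and a swing of 1.31 ± 0.16 (SE) on the log2 scale, against 1.87 on its second probe set. MRPL10, a protein of the mitochondrial ribosome, had its peak at position 11.8 with a swing of 2.57 ± 0.16. POX1, the acyl-CoA oxidase of peroxisomal fatty acid breakdown, had its peak at position 3.81 with a swing of 4.73 ± 0.42, and its mean intensity was 20.0 ± 1.12 (SD, n = 3) at position 2 against 0.305 ± 0.077 at position 10. At every other whole-number frequency that is not a multiple of the cycle's, limma called 0 genes. Each frequency was fitted alone, so the 12-interval cycle stayed in the residual, which holds such counts down. A period of 6 intervals gave 24 genes when fitted alone, against 699 when added to the 12-interval terms. The count of 0 is therefore no background rate.

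The time given to a gene depended on how its peak was defined. The fitted peak is the centre of a cosine, and the position of the highest mean often lay elsewhere. The shapes of courses were not classed, so the cause of this was not tested. By the fitted peak, the 2155 genes with a swing of at least 2-fold fell as 307 in positions 1 to 3, 654 in positions 4 to 6, 541 in positions 7 to 9 and 653 in positions 10 to 12. By the position of the highest mean of 3 arrays, the same genes fell as 823, 179, 860 and 293. The share assigned to positions 4 to 6 was therefore 30.3% by one definition and 8.31% by the other. The median distance between the 2 times was 0.930 intervals, and 75.3% of the genes had them within 1.5 intervals. Peak times below are fitted peaks unless the highest position is named.

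**Figure D1:**
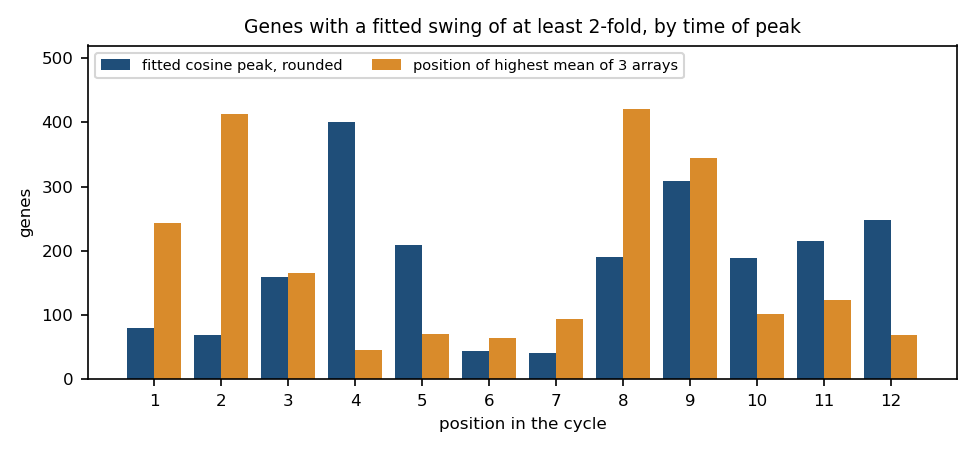
Number of genes with a fitted swing of at least 2-fold (vertical axis) at each position in the cycle (horizontal axis), by fitted cosine peak rounded to a position and by the position with the highest mean of 3 arrays. The fitted peaks were most frequent at position 4 (401 genes), whereas the highest means were most frequent at positions 8 (421 genes) and 2 (413 genes).

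Genes for making ribosomes were highest at positions 8 and 9. All 93 measured genes of ribosome biogenesis were called, 92 of them with a swing of at least 2-fold, and the list mean peaked at position 8.51 ± 0.24 (SD, n = 3 cycles) with a swing of 1.96 ± 0.28. NSR1, a nucleolar protein of ribosome assembly, swung by 3.62 ± 0.46 (SE) and DBP3, an RNA helicase, by 3.25 ± 0.37. Of 81 cytosolic ribosomal protein genes, 80 were called, all within 1.5 intervals of the list peak at position 9.09 ± 0.21 (SD, n = 3). Of the 81 genes 30 were read from probe sets that can match several transcripts, so their courses are not independent. RPS26A was not called on the probe set used, with a swing of 0.03 ± 0.14 (SE). Its second probe set was called (adjusted p = 7.8e-05 in limma), with a swing of 0.58 and a peak at position 9.19. The exception therefore depends on the probe set. RPL7B had the largest swing of the list, 3.41 ± 0.30, against 1.75 on its second probe set. RNA polymerases I and III (25 of 27 called) peaked at position 8.52 ± 0.26, and translation factors and tRNA synthetases (42 of 45) at position 9.42 ± 0.20. Amino acid biosynthesis (57 of 61, with 47 within 3 intervals) peaked at position 9.03 ± 0.10, led by the lysine genes LYS9 (3.85 ± 0.25, SE) and LYS4 (3.35 ± 0.26). Sulfur assimilation (24 of 25) peaked at position 9.77 ± 0.23 (SD, n = 3). No limma camera call of these lists as higher at a position held with an estimated correlation; sulfur assimilation held as lower at position 2 (adjusted p = 0.0436 with an estimated correlation). At the position most strongly called higher that adjusted p was 0.218 for ribosome biogenesis, 0.175 for cytosolic ribosomal proteins, 0.260 for RNA polymerases I and III, 0.218 for translation factors, 0.166 for amino acid biosynthesis and 0.144 for sulfur assimilation.

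The burst at positions 8 and 9 did not fall at the same position in each cycle. Ribosome biogenesis, RNA polymerases I and III, translation factors and amino acid biosynthesis each had their highest array at position 9 in cycle 1 and at position 8 in cycles 2 and 3. NSR1 stood at 7.19 at position 8 of cycle 1, and at 26.6 and 33.1 at that position in cycles 2 and 3. At position 9 the order was turned, with 31.2 in cycle 1, 3.15 in cycle 2 and 2.98 in cycle 3. The mean of NSR1 at position 8 was therefore 22.3 ± 13.5 (SD, n = 3). AAH1, an adenine deaminase, showed the same turn, with 4.66, 23.5 and 34.1 at position 8 and 25.7, 4.57 and 2.13 at position 9.

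Mitochondrial ribosome genes were called higher at positions 10 to 2, DNA replication genes at positions 9 to 12 and histone genes at positions 11 to 2 in camera with the preset correlation. With an estimated correlation positions 10 to 1 held for mitochondrial ribosomal proteins, and none held for DNA replication or for histones (adjusted p = 0.0617 for each at the position most strongly called higher). All 70 measured mitochondrial ribosomal protein genes were called with a swing of at least 2-fold, and the list mean peaked at position 11.8 ± 0.25 (SD, n = 3) with a swing of 2.13 ± 0.015. MNP1 had the largest swing (3.41 ± 0.19, SE) and MRPL33 the smallest (1.00 ± 0.15). The mean of mitochondrial import and folding genes (31 of 32 called) peaked at position 11.91 ± 0.28 (SD, n = 3). The called members more than 3 intervals from it were OM45, an outer membrane protein, at position 4.23, and TIM21 at position 4.59, the latter chosen after its values were seen. DNA replication and G1/S genes (42 of 51 called) peaked at position 11.1 ± 0.27, with RNR1, the large subunit of ribonucleotide reductase, at 4.37 ± 0.31 (SE) and the cyclin CLN1 at 3.41 ± 0.31. CTF4 of this list had a swing of 0.12 ± 0.17 and was not called. Of the 51 genes of this list 16 lie among the dimmest 25% of genes. Of the 10 histone genes in the list written in advance 4 were measured, all 4 were called, and HTB2 swung by 5.04 ± 0.21, between 19.5 ± 1.5 (SD, n = 3) at position 11 and 0.601 ± 0.020 at position 6. HHO1, the linker histone, swung by 1.68 ± 0.23 (SE) and HTB1 by 0.69 ± 0.12, both with their highest mean at position 2. The position most strongly called higher had an adjusted p of 0.0432 in camera with an estimated correlation for mitochondrial ribosomal proteins and of 0.0432 for mitochondrial import. Control probes for 25S ribosomal RNA moved with these lists, with a peak at position 12.0 and a swing of 0.556 (permutation p = 0.00025).

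The means of the respiration and mitosis lists were highest at positions 1 and 2. Oxidative phosphorylation genes (39 of 40 called, 15 with at least 2-fold) peaked at position 1.22 ± 0.53 (SD, n = 3) and TCA cycle genes (12 of 13) at position 0.84 ± 0.62. CYC1, cytochrome c, swung by 2.66 ± 0.21 (SE), and NDE2, an external NADH dehydrogenase, by 4.14 ± 0.32 with its peak at position 4.35. The mean of the mitosis list (28 of 31 genes called) peaked at position 1.94 ± 0.20 (SD, n = 3). However, only 16 of the 28 peaked within 1.5 intervals of it, and 10 peaked in positions 10 to 12. Of the 31 genes 14 lie among the dimmest 25% of genes. CHS2, the chitin synthase of the division septum, stood at 7.92 ± 0.60 at position 2 against 0.319 ± 0.057 at position 9, and BUD4, a bud-site protein, swung by 3.42 ± 0.20 (SE), against 2.55 on its second probe set. The camera adjusted p with an estimated correlation was 0.0119 for mitosis, 0.396 for oxidative phosphorylation and 0.466 for the TCA cycle.

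Genes of fat, storage carbohydrate and stress metabolism were called higher at different positions between 1 and 7. In camera with the preset correlation these were positions 1 to 7 for peroxisome genes, 2 to 7 for trehalose and glycogen and for autophagy, 1 to 5 for gluconeogenesis, 3 to 7 for redox and 4 to 7 for heat shock. With an estimated correlation only position 2 held for peroxisome genes, and no position held for the others. Peroxisome and fatty acid oxidation genes (39 of 42 called; 40 when adjusted over the list alone) peaked at position 3.80 ± 0.25 (SD, n = 3), with their highest mean at position 2. CTA1, the peroxisomal catalase, swung by 5.35 ± 0.47 (SE) and FOX2 of beta oxidation by 5.17 ± 0.50, whereas PEX19 had 0.15 ± 0.18 and was not called. All 20 trehalose and glycogen genes were called with at least 2-fold, peaking at position 3.86 ± 0.18 (SD, n = 3), and all 17 genes of gluconeogenesis, glyoxylate and acetate use were called, peaking at position 3.31 ± 0.30. The mean of the MCM and M/G1 list, of helicase subunits and genes of the end of division (18 of 21 called, 14 of them within 3 intervals), peaked at position 4.72 ± 0.26. EGT2, a daughter-separation protein, led it at 5.54 ± 0.42 (SE). Autophagy and vacuole genes (30 of 34) peaked at position 4.40 ± 0.090 (SD, n = 3), redox genes (32 of 33) at position 4.49 ± 0.12, pentose phosphate genes (12 of 13) at position 4.88 ± 0.29 and heat shock genes (22 of 23) at position 5.43 ± 0.062. Of the called members 8 of 12 pentose phosphate and 24 of 32 redox genes lay within 3 intervals of these peaks. SSA3, an Hsp70 chaperone, swung by 5.37 ± 0.31 (SE). Proteasome genes (27 of 33 called) moved less, with a list swing of 0.53 ± 0.035 (SD, n = 3) and a peak at position 4.05 ± 0.037. Ubiquitin genes (17 of 26) had a list swing of 0.47 ± 0.074 with a peak at position 4.11 ± 0.13. At the position most strongly called higher, the camera adjusted p with an estimated correlation was 0.0491 for peroxisome and 0.0436 for the MCM and M/G1 list. It was 0.260 for trehalose and glycogen, 0.101 for gluconeogenesis, 0.215 for autophagy, 0.155 for redox, 0.226 for pentose phosphate, 0.0775 for heat shock, 0.428 for proteasome and 0.466 for ubiquitin. Control probes moved with these lists: the 18S ribosomal RNA probes peaked at position 4.38 with a swing of 0.701 (permutation p = 0.00066), and the bacterial spike controls at position 3.62 with a swing of 0.520 (permutation p = 0.0112).

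**Figure D2:**
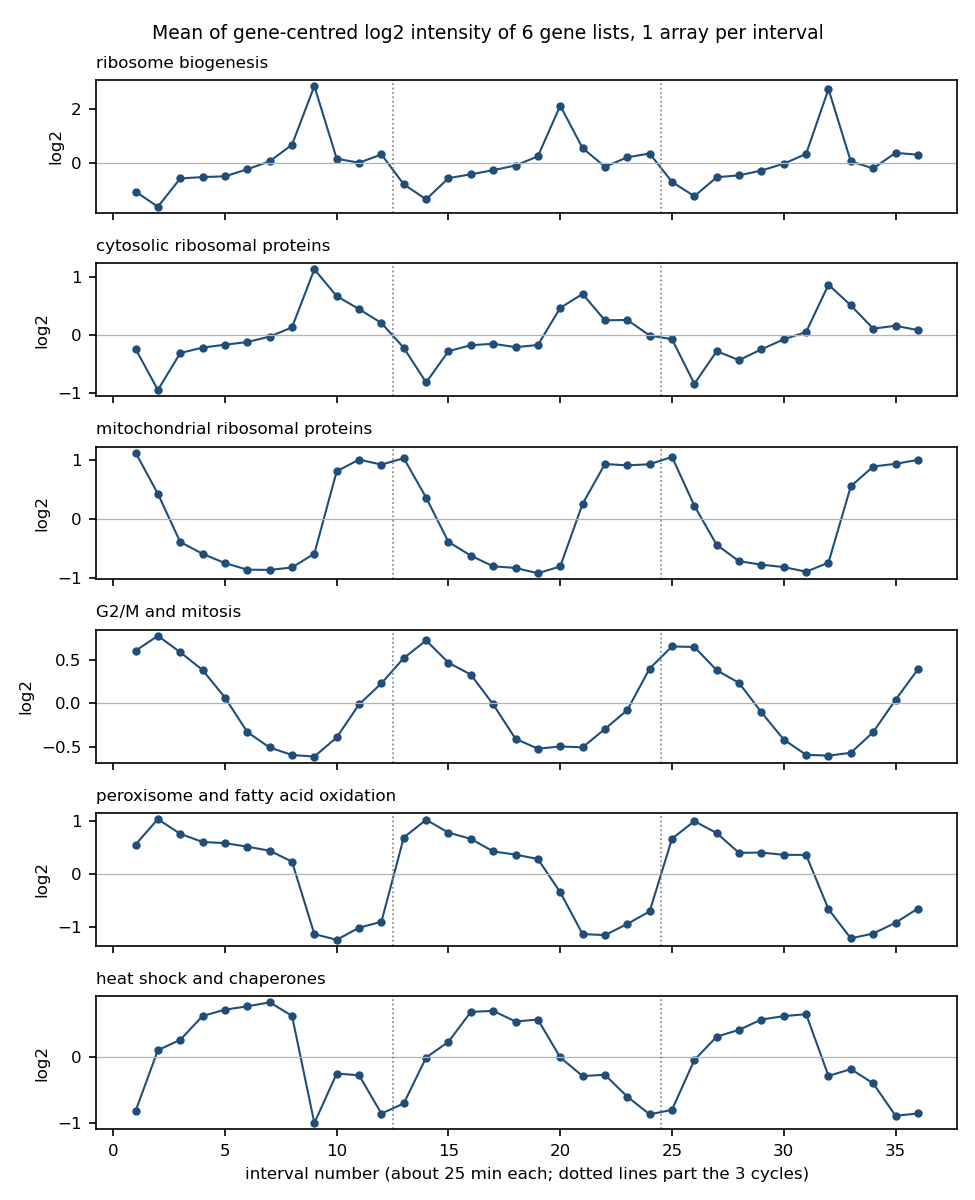
Mean of gene-centred log2 intensity (vertical axis) of 6 gene lists at each of 36 intervals (horizontal axis), 1 array per point, with dotted lines between the 3 cycles. Ribosome biogenesis rose in a short burst at interval 9 and then at intervals 20 and 32. The mitochondrial ribosome list (fitted swing 2.13) stood 0.965 to 1.18 log2 above the mean of its other positions at positions 10 to 1. The peroxisome list (fitted swing 1.97) stood 1.11 log2 above at position 2 and then fell, to 0.399 at position 7.

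Other lists had a weak common course or none. Glycolysis and fermentation genes (15 of 20 called) had peaks spread over the cycle and a list swing of 0.11 ± 0.042 (SD, n = 3). HXK2, a hexokinase, peaked at position 10.8 and GLK1, glucokinase, at position 3.78, while the enolase ENO2 had a swing of 0.15 ± 0.13 (SE) and was not called. Camera called this list higher at position 1, with an adjusted p of 0.0252, and the adjusted p was 0.475 with an estimated correlation. Ergosterol and lipid genes (32 of 33 called) had ERG4 at position 10.7 and INO1, of inositol synthesis, at position 3.11. Mating and haploid genes (18 of 20 called) had the pheromone gene MF(ALPHA)1 at position 10.0. RME1 of this list, a repressor of meiosis, was at position 4.63, and both had swings above 3 log2. Of these 20 genes 16 lie among the dimmest 25% of genes. Of 13 hexose transport genes 9 were called, led by HXT5 with 2.20 ± 0.15, and the camera adjusted p with an estimated correlation was 0.249. Of 35 meiosis and sporulation genes 25 were called, or 23 when adjusted over the list alone, and the list mean peaked at position 3.52 ± 0.21 (SD, n = 3). IME1, the inducer of meiosis, led this list with 3.75 ± 0.27, and the camera adjusted p of 0.0205 at position 5 became 0.198 with an estimated correlation. Among 12 genes often used as references 9 were called, with TUB1 at 1.78 ± 0.14 and IPP1 at 0.04 ± 0.10. For all lists other than the peroxisome and meiosis lists, the count adjusted over the list alone equalled the count over all genes.

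Camera with a preset correlation of 0.01 called 26 of 29 lists higher at some position, in 111 of 348 pairs of list and position, against 13 pairs and 5 lists with an estimated correlation. Random regroupings of the arrays gave a median of 78 such pairs, so the preset count measures mainly that the members of a list move together. A test added after this was seen fitted the cosine to each list mean and permuted the arrays 100000 times. It passed for 27 of the 29 lists after Benjamini-Hochberg adjustment, the reference genes included, and not for glycolysis (adjusted p = 0.768) or the mating list (adjusted p = 0.129).

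The intervals between list peaks differed in how much they varied between cycles. The mitochondrial ribosomal protein list peaked 2.70 ± 0.037 intervals (SD, n = 3) after the cytosolic one, which is 67.6 min at 25 min per interval. The peroxisome list peaked 4.01 ± 0.043 intervals after the mitochondrial ribosomal protein list. All lags here are between fitted peaks, and the highest arrays were spaced otherwise. For the cytosolic list the highest array was at positions 9, 9 and 8 in cycles 1, 2 and 3. It was at position 1 for the mitochondrial list and at position 2 for the peroxisome list in each cycle. Mitosis followed DNA replication by 2.89 ± 0.19 intervals, and the MCM and M/G1 list followed mitosis by 2.78 ± 0.089. Cytosolic ribosomal proteins followed ribosome biogenesis by 0.578 ± 0.065 intervals. Heat shock followed the peroxisome list by 1.63 ± 0.19 intervals, and oxidative phosphorylation followed mitochondrial ribosomal proteins by 1.75, 1.34 and 1.20 intervals in cycles 1, 2 and 3. An exact sign-flip permutation test over 3 cycles gave p = 0.25 for each, the smallest p that 3 cycles allow, and the pairs of lists were chosen after their peak times were seen.

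**Figure D3:**
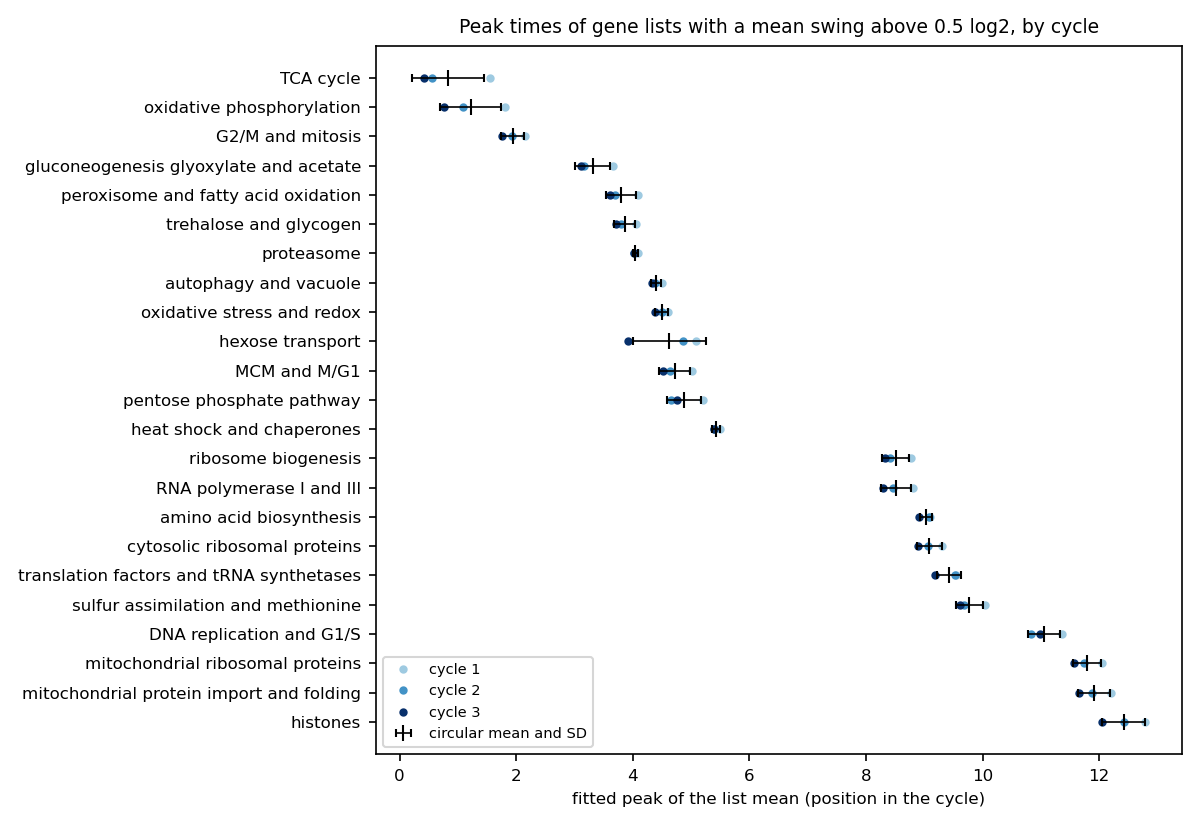
Fitted peak of the list mean (horizontal axis, position in the cycle) for the 23 gene lists with a mean swing above 0.5 log2 (vertical axis), with a point for each cycle and a bar for the circular mean and SD of the 3 cycles. Ribosome biogenesis peaked at 8.51, mitochondrial ribosomal proteins at 11.8 and peroxisome genes at 3.80.

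In each part of the cycle, the rule fixed in advance took the 6 genes with the largest swings. With fitted peaks in positions 1 to 3, AIM20 swung by 3.96 ± 0.18 (SE), YNL058C by 3.46 ± 0.20, HMX1, a haem oxygenase, by 3.25 ± 0.29 and REE1 by 3.16 ± 0.21, beside CHS2 and BUD4. With peaks in positions 4 to 6, TKL2, a transketolase, swung by 6.55 ± 0.45, CTT1, the cytosolic catalase, by 6.48 ± 0.49, HEF3, a translation elongation factor, by 6.29 ± 0.33, GRE1 by 6.14 ± 0.34 and PIR1, a cell wall protein, by 5.68 ± 0.36. With peaks in positions 7 to 9, AAH1 swung by 3.52 ± 0.53, MUP1, a methionine permease, by 3.44 ± 0.30, GPP1, a glycerol phosphatase, by 3.29 ± 0.27 and IMD4, of guanine nucleotide synthesis, by 3.28 ± 0.40. With peaks in positions 10 to 12, PRY2 swung by 5.04 ± 0.28, FET3, the iron uptake oxidase, by 5.00 ± 0.25, TOS6 by 4.78 ± 0.23 and SCW10, a cell wall protein, by 4.62 ± 0.23. The second probe set of SCW10 gave 1.08.

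Most isoenzyme pairs differed in their course, but unrelated pairs were not tested, so this is not shown to be particular to isoenzymes. Of 36 pairs fixed in advance, 31 differed (limma on the log2 difference of the pair, adjusted p under 0.05). In 12 pairs both genes were called with peaks more than 3 intervals apart. Of all genes 78.8% cycled, and peak times shuffled among cycling genes put neighbouring genes a median of 3.04 intervals apart. A called difference can also be one of swing: LYS20 and LYS21 were called with peaks 0.018 intervals apart. The transketolases differed most, with TKL1 at position 10.4 and TKL2 at position 4.97, and a swing of their difference of 8.95 ± 0.54 (SE). The swing of the difference was 6.01 ± 0.48 for the ribonucleotide reductase subunits RNR1 and RNR3, 5.09 ± 0.35 for the alcohol dehydrogenases ADH1 and ADH2, and 4.43 ± 0.28 for the 6-phosphogluconate dehydrogenases GND1 and GND2. RNR3 lies among the dimmest 25% of genes and, like TKL2, was read from a probe set that can match several transcripts; the second probe set of TKL2 gave a swing of 6.86 for that gene. It was 4.20 ± 0.39 for the acetyl-CoA synthetases ACS1 and ACS2, 4.08 ± 0.33 for the cytochromes c CYC1 and CYC7, 4.06 ± 0.33 for the branched-chain aminotransferases BAT1 and BAT2, and 3.97 ± 0.37 for the transaldolases TAL1 and NQM1. ADH2 stood at 89.0 ± 4.17 (SD, n = 3) at position 2 and 5.80 ± 0.71 at position 10, whereas ADH1 stood at 71.8 ± 4.64 at position 1 and 21.7 ± 3.21 at position 6. Pairs that were not called included SOD1 and SOD2, with a difference of 0.11 ± 0.19 (SE), and ASN1 and ASN2, with 0.23 ± 0.23; these 2 pairs were chosen after their values were seen.

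**Figure D4:**
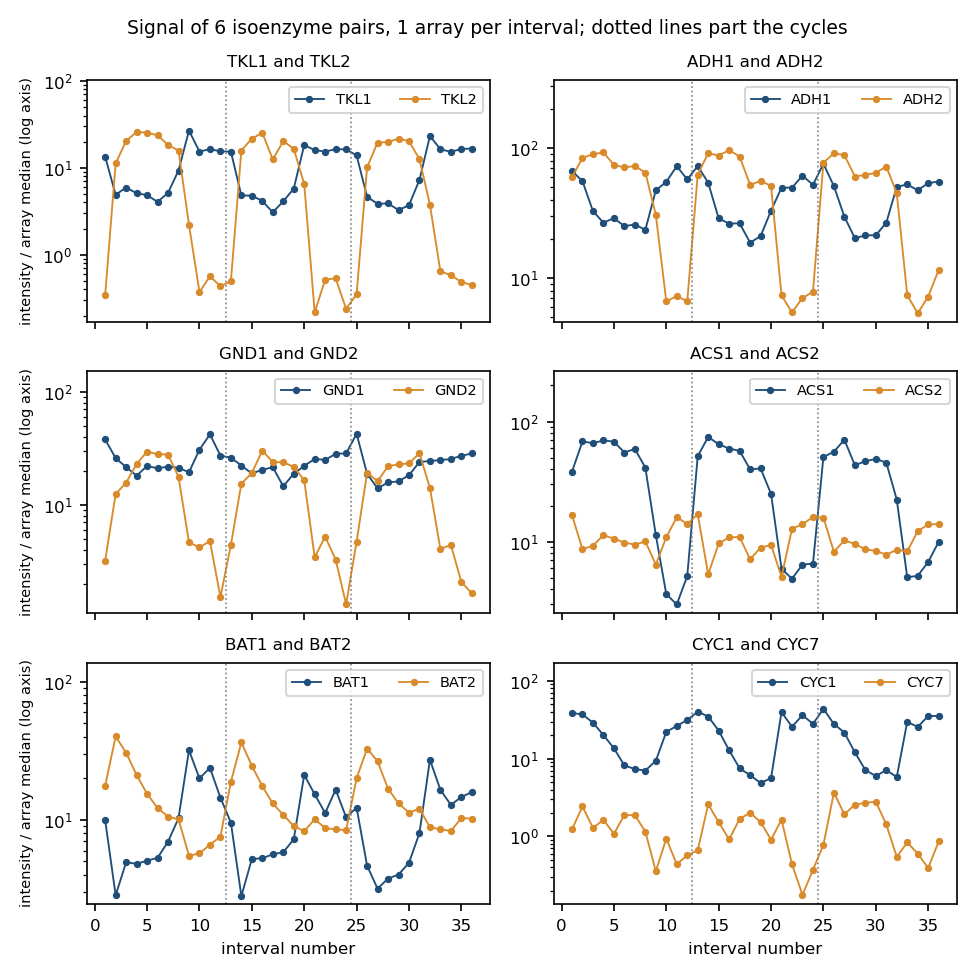
Intensity divided by the array median (vertical log axis) of 6 isoenzyme pairs at each of 36 intervals (horizontal axis), 1 array per point, with dotted lines between cycles. TKL2 was high where TKL1 was low in each cycle; the levels of different probe sets are not comparable, only their courses.

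A second harmonic, which marks a departure from a single cosine, was called for 699 genes, and in 174 of them it exceeded the 12-interval swing. It is not a measure of sharpness. It was called for CTA1 and FOX2, and not for NSR1 (adjusted p = 0.591 in limma) or DBP3 (0.627), which rose in the burst at positions 8 and 9. The burst of NSR1 changed position between cycles, and a term fitted over all cycles does not allow for that. The missing calls therefore do not show how the term relates to sharpness. HXT2, a glucose carrier, had a 6-interval swing of 2.65 against 0.86 for 12 intervals. BSC1 had 1.77 against 1.19, ANS1 1.53 against 1.39, IZH4 1.53 against 1.20 and NCA3 1.51 against 1.22. The count of two-peaked genes fell to between 200 and 265 when a cycle was left out. BSC1 and ANS1 lie among the dimmest 25% of genes.

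Few genes were called as differing between cycles in level, or in swing or phase of the cosine. NSR1 and AAH1, whose burst moved between cycles, were called by neither test, and no shift of timing was simulated. The small counts therefore do not show that the cycles agreed in timing. The level of 3 genes differed between cycles (limma, position as a factor), where 324 had an unadjusted p under 0.05; the count was 0 to 7 with a cycle left out. HXT14, a hexose carrier family member among the dimmest 25% of genes, was higher in cycle 3 than in cycle 1 by 0.72 on the log2 scale (adjusted p = 0.00307 in limma). SPS100, a spore wall protein, fell by 0.86 and PUN1, a membrane protein, fell by 0.67 (adjusted p = 0.00116 in limma for each). Cycles were successive, so cycle and elapsed time cannot be told apart. The swing or phase of 2 genes differed between cycles, YPR145C-A, which lies among the dimmest 25% of genes (adjusted p = 0.00293 in limma), and TFB5, a subunit of a transcription factor (adjusted p = 0.0344 in limma), with 261 genes at an unadjusted p under 0.05. The count fell to 1 under quantile normalization, without the dimmest genes and with any of 24 of the 36 arrays left out, so it is fragile. Neither had a 12-interval swing that was called over all arrays.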

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

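The tests of a constant shorter period and of shared ribosomal RNA, trimmed-mean scaling, the swing of the trimmed mean itself, the exchange of what the 12-interval cosine leaves, the leaving out of arrays in turn for the period and the gap of the ribosomal RNA probes within each cycle were chosen only after the result was seen. Chance was tested with 100 regroupings of the arrays, the real one included; for the comparisons between cycles, cycles were exchanged within each position. It can be excluded for the cycling genes (1 of 100 regroupings as high; 4456 genes against at most 0 otherwise), for cycling genes with at least 2-fold swing (1 of 100; 2155 against 0) and for isoenzyme pairs (1 of 100; 31 against 10). For the genes differing between cycles (1 of 100, 3 against 0) chance is only argued against. The same holds for the genes whose swing differs between cycles (1 of 100, 2 against 0). Both counts are small and reached 0 in a run with a cycle left out. The exchange also breaks up any shift of timing shared within a cycle, so it does not test these counts beside such a shift. For two-peaked genes, meaning those with a called second harmonic, 3 of 100 regroupings gave as many as 699 and the highest other gave 1651, but these break up the 12-interval cycle as well and do not test a term beside it. Chance can be excluded for them by exchanging only what the 12-interval cosine leaves (1 of 100 exchanges as high; 699 against at most 2). For gene lists by position it can be excluded at 1 of 100, with 111 against 97, but the median of the regroupings was 78, so most such calls arise without any ordering of the arrays.

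The genes whose swing differs between cycles numbered 2, by an interaction test. YPR145C-A had an adjusted p of 0.00293 and TFB5 an adjusted p of 0.0344. The count was 2 or 1 depending on the scaling and on single arrays, and 0 or 1 with a cycle left out.

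Signal outside the tested genes also followed the cycle. Of 2443 unlisted probe sets 337 cycled with at least 2-fold swing, as did 70 of 328 probe sets of several genes, against 1 of all 60 control probe sets and 0 of the 37 bacterial and mouse controls among them.

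Control probes for ribosomal RNA followed the cycle, with a swing of 0.701 for 18S (permutation p = 0.00066) and 0.556 for 25S (permutation p = 0.00025), and the bacterial spike controls had a mean swing of 0.520 (permutation p = 0.0112). Among measures of whole arrays, the median of named genes followed the cycle with a swing of 0.055 (permutation p = 0.0278), while the trimmed mean (permutation p = 0.431) and the ratio of the 3' to the 5' actin probes (permutation p = 0.944) were not called. Scaling by the array median stays open, although the written rule would have excluded it: the swings under trimmed-mean scaling were at least 0.959 of the original, but the trimmed mean itself swung by only 0.054, too little to have taken either swing below 0.5 of its value. One shared amount of ribosomal RNA carried into the hybridised material stays open too: the 18S and 25S probes peaked 4.36 intervals apart, where the written rule would have excluded it at more than 3, but the gap was 4.51, 5.97 and 2.75 in the 3 cycles, an SD of 1.61. No biological explanation was tested.

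List peak times moved earlier from cycle 1 to cycle 3 in 23 of 23 lists with a swing above 0.5, by a mean of -0.485 intervals, about -12.1 min; the lists share the same arrays and are not independent. Scaling is argued against only for differences that quantile normalization removes, since the mean was -0.477 under it. That step moved the median of all genes on an array by at most 0.123 log2. Beside list swings above 0.5 this is small, so larger scaling errors were not tested. A single array out of place is argued against as the whole cause, since leaving out any array of cycle 1 or 3 left at least -0.358, the value without the position 2 array of cycle 3. A constant period shorter than 12 intervals cannot be told apart from an uneven drift. The mean step was -0.329 from cycle 1 to 2 and -0.156 from cycle 2 to 3, a difference of -2.50 standard errors over lists, which the written rule would have read as uneven. It was left open because the lists share arrays, and the difference was only -0.328 standard errors when arrays were left out in turn. No biological explanation was tested.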

How the results depend on the processing

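Trimmed-mean scaling, the best-fitting common period, single arrays left out, the run without position 8, the permutation of list means and, for named genes, the alternatives other than quantile scaling, replicate block, left-out cycles and second probe sets were chosen after seeing the data. Cycling genes numbered from 3476 to 4509 over the alternatives that kept all cycles, and from 3912 to 3963 with a cycle left out. The cycling genes with at least 2-fold fitted swing numbered from 1726 (without the dimmest genes) to 2281 (with the smaller pseudocount), and from 2097 to 2238 with a cycle left out. Without position 8, where arrays of different cycles correlated least, the cycling genes numbered 4262 and the cycling genes with at least 2-fold fitted swing 1975. At periods that are no harmonic of 12 intervals the highest count was 0 for both. Each period was fitted without the 12-interval terms, so the cycle stayed in the residual and these counts are no background rate. The two-peaked genes fell to between 200 and 265 with a cycle left out, where fewer arrays enter, and lay between 603 and 796 with single arrays left out. The genes differing between cycles numbered 0 to 7 with a cycle left out; the cause was not tested. The genes whose swing differs between cycles numbered 1 under quantile normalization, 1 without the dimmest genes, 1 under trimmed-mean scaling, 0 to 1 with a cycle left out and 1 to 2 with single arrays left out, with 1 for 24 of the 36 arrays; the cause was not tested. Gene lists by position fell from 111 to 13 pairs with an estimated correlation, which allows for members that move together. The peak position of cycling genes, as the share in positions 4 to 6, moved from 30.3% to 8.31% with the position of highest mean; the cause was not tested. The list peak times, as the lag from cytosolic to mitochondrial ribosomal proteins, moved from 2.70 to 2.65 under quantile normalization and to 2.74 with standardized values, more than their SD of 0.037; the cause was not tested. The scalings moved the median of all genes on an array by up to 0.123 (quantile), 0.125 (same median) and 0.170 (trimmed mean) on the log2 scale. Among named genes 1345 comparisons with an alternative kept their side of the threshold, 15 lost it, 9 gained it, and none moved its peak by more than 3 intervals while called; 19 of the peak times and lags moved by more than their SD. Deviations from the position mean had a median correlation of 0.016 between arrays of the same cycle and -0.016 between arrays of other cycles. The lowest values were -0.680 and -0.501. These medians do not show that arrays of a cycle are independent, since list peak times moved together between cycles. With the replicate block, cycling genes numbered 4442 against 4456, those with at least 2-fold swing 2155 and two-peaked genes 680. List pairs then numbered 111 and isoenzyme pairs 29 against 31. Signal near the floor limits the genes in the dimmest 25%.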

Other observations

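The split of neighbouring genes by direction of transcription, the shares of called second harmonics without each cycle, and, for the meiosis list, the estimated correlation, the counts of dim and of called genes and the mean of its brighter members were chosen only after the result was seen. Neighbouring genes on a chromosome tended to peak at similar times. Over 3088 adjacent pairs of cycling genes the median difference in peak time was 2.69 intervals, below all of 1000 shuffles of peak times among these genes (shuffle median 3.04, lowest 2.83), so chance order is argued against. Overlapping genes do not account for it, since the 3068 pairs that do not overlap had a median of 2.71 (lowest shuffle 2.85). Pairs transcribed away from each other had a median of 2.25 intervals and pairs on one strand 2.76, while pairs transcribed towards each other had 3.09, not below the shuffles. A shared promoter region is a candidate explanation for the divergent pairs, which was not tested; genes are not independent replicates.

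A called second harmonic was most frequent among genes with fitted peaks in positions 4 to 6, at 30.1% of them against 14.3% of the rest (Fisher exact p = 7.9e-17, which treats genes as independent). It was least frequent in positions 7 to 9, at 8.69%. The burst at positions 8 and 9 did not fall at the same position in each cycle, and its effect on these shares was not tested. With a cycle left out, positions 4 to 6 remained highest at 15.5%, 14.3% and 11.925%, against 12.3%, 6.95% and 8.90% in positions 1 to 3. Of the genes with fitted peaks in positions 4 to 6, 26.8% had their highest mean there. The figure was 94.8% for positions 1 to 3, 99.8% for positions 7 to 9 and 42.9% for the remaining positions. A highest mean away from the fitted peak can itself be a departure from a cosine. Part of the high share may therefore follow from grouping by fitted peak, which was not tested. Only chance is argued against, and the call marks a departure from a cosine and does not measure how sharp a course is.

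The mean of the meiosis and sporulation list followed the cycle (adjusted permutation p = 1.16e-05), with a fitted peak at position 3.52. Noise of dim genes is argued against as the whole cause, since the mean of the 8 members above the dimmest 25% of genes also followed it, with a swing of 1.12 and a peak at position 4.27 (permutation p = 0.0001). Most genes followed the cycle, so this does not set the list apart from other genes.

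The list was also called higher than other genes in camera, with its smallest adjusted p at position 5, although its highest mean lay at position 2, which was called as well (adjusted p = 0.0411). For this call noise of dim genes may account and stays open: with dim genes left out the smallest adjusted p was 0.0113, which the written rule would have read as excluding noise, but that rule rested on the preset correlation, and the adjusted p was 0.183 with an estimated correlation. A share of cells in meiosis stays open too, since the 9 middle-meiosis genes SPS1, SPS2, SPS4, SMK1, DIT1, DIT2, SSP1, SSP2 and NDT80 had a median swing of 0.65 log2, which the written rule would have read as excluding it, but 8 of them lie among the dimmest genes, where a swing is understated. Of 6 called among them 3 peaked within 2 intervals of position 5, and also of the list peak, while NDT80 (10.8), SPS1 (10.5) and SPS4 (0.82) peaked elsewhere. No biological explanation was tested beyond this.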
